A study of Ovis aries with 13 samples.

How the data were processed

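Gene expression was measured in blood lymphocytes of 3 female sheep infected with Haemonchus contortus, the barber's pole worm, a blood-feeding nematode of the sheep stomach. The labels call the cells T lymphocytes. Per the labels' protocols they were taken from peripheral blood by density centrifugation, with no sorting step described, so that other white cells may have been carried along. Total RNA was extracted with TRIzol, purified on columns, amplified, labelled with Cy3 and hybridised to single-colour Agilent arrays. The labels name sheep 2, 3 and 5 and days 0, 3, 30 and 60 after infection. The treatment protocol in the labels gives ranges of days around the second and the third sampling, so the printed days 3 and 30 are nominal. Each sheep and day had 1 array, except sheep 5 at day 0, which had 2. Those 2 arrays had a correlation of 0.9985 across probes and an SD of their log2 difference of 0.159, and they were averaged to 1 sample, which gave 12 samples from 13 arrays. Samples of uninfected sheep at matched days were not analysed here, so that time after infection, age and season change together.

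Per the file headers, the 13 scanner files were made with Agilent Feature Extraction 10.7.1.1, which subtracted the background of each spot and removed spatial trends to give the processed signal, an intensity that was not yet scaled between arrays. The authors also deposited a value table on a log2 scale for 33021 of the 43525 probes. Per the submitters' processing notes, Feature Extraction and limma were used, and further steps are not given in the sources used here. The 13 columns of that table had medians from 7.71 to 7.72 and minima between 5.68 and 5.76, so they had been brought to nearly the same distribution. Their background correction stayed unknown. They were levels, not ratios, and were not centred by probe. Rank correlations of each column with its own scanner file were at least 0.99989 for 11 columns. For day 0 of sheep 2 and day 0 of sheep 3 they were 0.947 and 0.927, so these 2 columns hold values other than those of the scanner files used here. The table was therefore used as an alternative.

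Probes had identifiers and sequences of 60 bases, and the scanner files gave neither gene names nor coordinates for any of the 43525 probes. None of the identifiers matched the 35057 genes of the sheep reference table used here. The files do not pair the probes with genes. The 29 gene lists fixed before the data were examined, including the cell type markers, were therefore not tested, and probes are reported by their identifier and sequence. The rule for named genes, fixed before the data were examined, took those past the threshold with the same sign in all 3 sheep and the largest rise or fall, or, where fewer than 5 passed, those with the smallest unadjusted p. It was applied to probes in place of genes, with 2 rising and 2 falling probes in each comparison. A probe chosen by this rule is not reported here.

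The log2 processed signal of each array was reduced by the 75th percentile of that array, so that a level of 0 is the signal at that percentile. Control spots and spots marked as outliers by the scanner software were left out, and the spots of a repeated probe were averaged. Probes were tested if they were well above background on every array of at least 1 time point, which held for 33595 probes. 25760 probes were well above background on all 13 arrays. Linear models were fitted with limma 3.58.1 in R 4.3.3, with the 4 time points and the sheep as a block, to all 12 samples with 1 estimate of the spread per probe and 6 residual degrees of freedom. The series design states that each sheep was followed over time, which is the source of the pairing. Deviations from the time point means correlated between samples of the same sheep with a median r of 0.275 over 18 pairs (0.016 to 0.733). Between samples of different sheep the median r was -0.113 over 36 pairs. Each time point was centred over 3 sheep, which by itself pushes values between different sheep below 0. Some pairs of the same sheep also shared a slide, so the difference between the 2 medians is no separate support for the pairing. The 5 contrasts (day 3, 30 and 60 against day 0, day 30 against day 3, day 60 against day 30) were tested two-sided with limma's moderated test, and the change over the 4 time points with its moderated F-test. P-values were adjusted after Benjamini and Hochberg, with a threshold of 0.05. Where a probe was not well above background on any array of a time point, its fold is given as a lower bound ("at least"). The bound sets the mean of the brighter time point against the mean, over the dim time point's arrays, of the higher of the probe's own value and the lowest signal among probes well above background.

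The arrays lay on 4 slides. Slide 1 held days 0 and 3 of sheep 2 and 3, slide 2 held day 60 of sheep 2 and 3 and day 3 of sheep 5, slide 3 held day 30 of all 3 sheep and day 60 of sheep 5, and slide 4 held both day 0 arrays of sheep 5, scanned in a session of their own. Slide was entered as a fixed block and as a random block (duplicateCorrelation), and contrasts were fitted within a slide where residual degrees of freedom remained. The other alternatives fixed before the data were examined were a fit with no sheep block, quantile, median and normexp scaling (offset 50), the authors' table, no filter or a stricter filter on dim probes, a trended and robust prior, array weights, fits to the samples of 2 time points alone, either array of the repeated sample alone, each sheep left out, and other thresholds. Chosen after seeing the data were fits without slide 1, fits without day 0 of sheep 2 and 3, the table without slide 1 arrays, without the sheep block and without each sheep, a GC correction in the fit with the sheep block, and each sample left out.

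The fit was tested on simulated data that used the means and residual SDs of 33032 probes. With 200 probes changed at day 30, the fit for day 30 against day 0 recovered 23.9% of the probes changed 2-fold, 65.7% of those changed 4-fold and 93.9% of those changed 8-fold, with 8 false calls among 130. With a slide 1 effect added to every simulated probe, it recovered 4.48%, 37.3% and 77.3%, with 10 false calls among 89. With slide as a fixed block 0% was recovered at each of these sizes in both simulations. With no change simulated, it made 0 calls in each of the 5 contrasts. The simulated noise was independent between probes and arrays, so these false calls do not give the error rate on the real arrays. The number of arrays limits the precision of all values. The 75th percentile of the processed signal lay between 262.4 and 754.4 units, and between 63.55% and 80.38% of spots were well above background. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.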

Results

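The data set was a time course of gene expression in blood lymphocytes of 3 sheep before (day 0) and 3, 30 and 60 days after infection with Haemonchus contortus. The design asked which transcripts change in these cells as the infection goes on. Each time point had 3 samples, 1 from each of sheep 2, 3 and 5, and each comparison was made within sheep. Signals are given as log2 values relative to the 75th percentile of the same array, as means ± SD (n = 3), and changes as log2 differences with the standard error (SE) of the limma fit. Probes are named by the identifiers of the array design, because the files do not pair them with genes.

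Slide 1, which held days 0 and 3 of sheep 2 and 3, differed from the other slides in the scanner's own quality measures. The coefficient of variation of the spike-in spots was 9.785% to 13.94% on its 4 arrays and 2.577% to 4.682% on the other 9. The scanner software marked 146 to 264 outlier spots per array on slide 1 and 13 to 35 on the others. The share of spots well above background was 63.55% to 70.09% on slide 1 and 73.6% to 80.38% elsewhere. The software rated all 4 arrays of slide 1 for evaluation and the other 9 as in range. Day 30 of sheep 2 and 3 lay on slide 3 and their day 60 on slide 2. For sheep 2 and 3, each comparison except day 3 against day 0 is therefore also one between slides. Sheep 5 had no array on slide 1, but lay on slide 4 at day 0, slide 2 at day 3 and slide 3 later. Its comparisons, except day 60 against day 30, are thus also between slides.

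**Figure D1:**
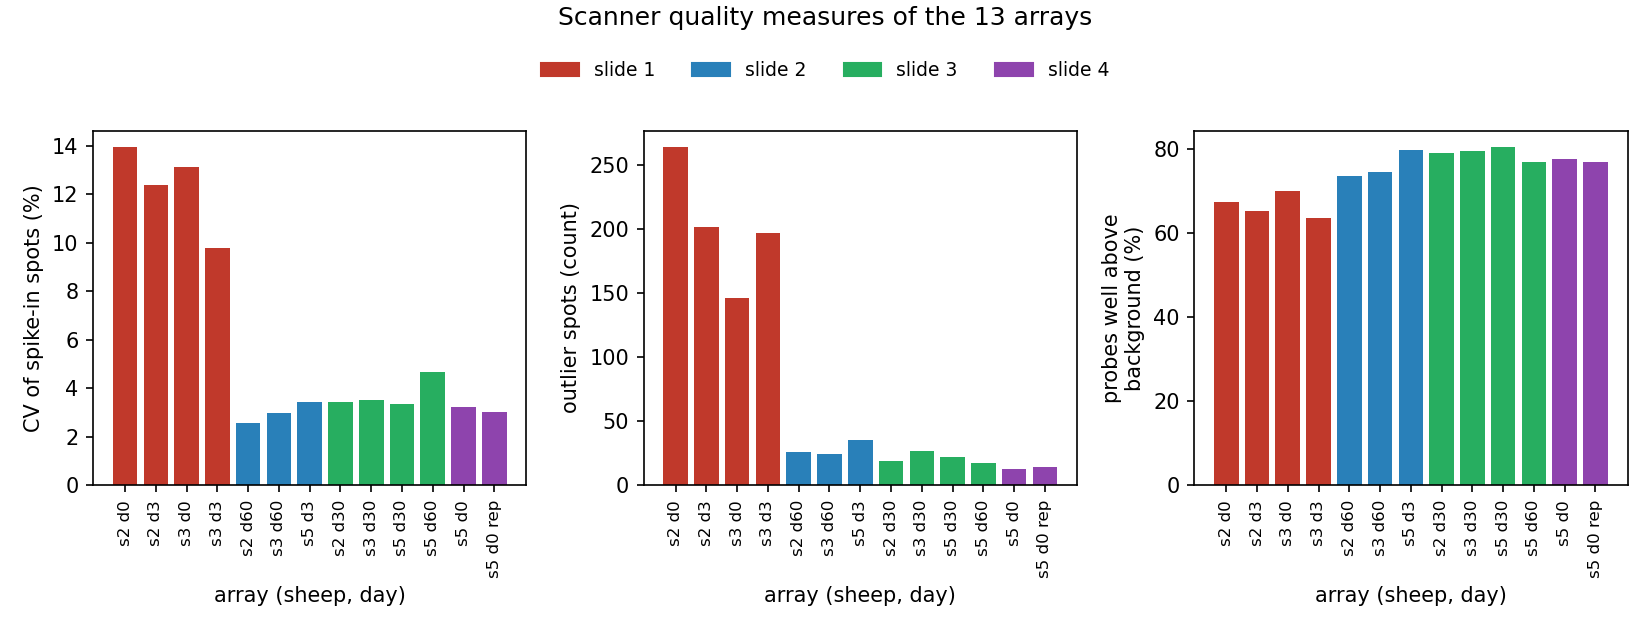
Bars give, for each of the 13 arrays (sheep s, day d, rep for the repeat array), the coefficient of variation of the spike-in spots in percent, the count of outlier spots and the percent of spots well above background, coloured by slide. The 4 arrays of slide 1 have 146 to 264 outlier spots and the other 9 have 13 to 35.

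At day 30, 829 probes differed from day 0, of which 756 were higher and 73 lower. The rises had a median of 1.504 on the log2 scale and the falls a median of 1.05 (median changes of 0.507 and -0.339 for the same probes in the authors' table), and 755 of the 756 higher probes and all 73 lower probes had the same sign in all 3 sheep. Probe CUST_4557_PI425336670 (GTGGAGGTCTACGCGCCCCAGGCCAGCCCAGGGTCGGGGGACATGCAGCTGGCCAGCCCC) rose from -2.35 ± 0.98 to 2.42 ± 0.18, by 4.76 (SE 0.99, adjusted p = 0.0479). Its signal was low on all arrays of slides 1 and 4 and high on all arrays of slides 2 and 3, including day 3 of sheep 5, where it stood at 2.20. Its change with slide as a fixed block was -1.53 (SE 1.11).

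Among the probes that fell at day 30, CUST_28714_PI425336670 was well above background on all 4 arrays of day 0, at -3.54 ± 0.26, and on none of day 30. It was at least 4.73-fold lower at day 30 (adjusted p = 0.0395), but its log2 change was only -0.259 after normexp and quantile scaling and -0.837 in the authors' table. On slide 1 itself it stood at -3.84 at day 0 and -5.01 at day 3 in sheep 2 and at -3.40 and -6.62 in sheep 3, and in sheep 5 it stood at -7.90 at day 3. Probe CUST_18639_PI425336670 fell by 3.72 on the log2 scale (SE 0.62, adjusted p = 0.0395), from -0.96 ± 0.72 to -4.68 ± 1.35, and stood at -2.20 ± 0.70 at day 60. It was well above background on 2 of the 3 arrays of day 30, and its change was -0.775 (adjusted p = 0.0761) after normexp and quantile scaling and -1.573 (adjusted p = 0.0996) in the authors' table. On slide 3, which held both days of sheep 5, it stood at -4.73 at day 30 and -1.44 at day 60.

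The count at day 30 depended on the model, on the filter and on single sheep. It was 1 with no sheep block, 0 with slide as a fixed or random block, 0 without sheep 2, 0 without sheep 3 and 4182 without sheep 5. The slide block left 3 residual degrees of freedom and a median SE of 0.682, against 0.239 with the sheep block alone. Of single samples left out, the count was 0 without day 0 of sheep 2, day 3 of sheep 2, day 3 of sheep 3, day 30 of sheep 2, day 30 of sheep 3 or day 60 of sheep 3. It was 2 without day 60 of sheep 2, 4 without day 0 of sheep 3, 478 without day 60 of sheep 5, 797 without day 3 of sheep 5, 1873 without day 0 of sheep 5 and 2916 without day 30 of sheep 5. It was 2 with no filter on dim probes and 0 in the fit to the samples of days 0 and 30 alone, which left 2 residual degrees of freedom. The split into 756 higher and 73 lower probes was 178 and 87 after normexp and quantile scaling, and without slide 1, a fit that left sheep 5 as the only sample of day 0, 314 probes passed (77 higher, 237 lower). At day 30, 20 probes passed in the authors' table (12 higher, 8 lower), and without its slide 1 columns 401 (318 higher, 83 lower), of which 116 higher and 2 lower probes were also called in the scanner values.

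Day 30 against day 3 gave 2185 changed probes, with 1879 higher and 306 lower. This was the highest count of the 5 contrasts with 75th percentile scaling, whereas with quantile scaling day 30 against day 0 gave 1070 and day 30 against day 3 gave 254. The rises had a median of 1.38 and the falls of 0.86 on the log2 scale. Probe CUST_13320_PI425336670 rose by 5.20 (SE 1.20, adjusted p = 0.044), by 6.87 in sheep 2, 6.86 in sheep 3 and 1.86 in sheep 5. It was low on the 4 arrays of slide 1, between -2.37 and -1.99, and between 3.14 and 5.01 on the other 9. Probe CUST_26784_PI425336670 rose by 4.59 (SE 0.83, adjusted p = 0.0364) and by 2.37 in sheep 5. At day 3 it was not well above background in sheep 2 and 3, so the mean rise is partly set against background. The rise was 1.64 (adjusted p = 0.035) after normexp and quantile scaling and 2.881 (adjusted p = 0.00806) in the authors' table. After quantile scaling it was 4.417 and did not pass (adjusted p = 0.0521). Probe CUST_18639_PI425336670 fell by 3.48 on the log2 scale (SE 0.62, adjusted p = 0.0364). Its change was -0.661 (adjusted p = 0.0839) after normexp and quantile scaling and -1.518 (adjusted p = 0.0404) in the authors' table. Probe CUST_32966_PI425336670 (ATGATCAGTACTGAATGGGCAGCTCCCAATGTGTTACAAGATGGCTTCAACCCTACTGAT) fell by 2.01 on the log2 scale (SE 0.40, adjusted p = 0.0387), from 5.04 ± 0.60 to 3.03 ± 0.24, with changes of -1.07, -2.43 and -2.53 in sheep 2, 3 and 5.

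For sheep 2 and 3 this contrast sets slide 3 against slide 1, and for sheep 5 slide 3 against slide 2. The count of 2185 was 0 with no sheep block, 0 with no filter on dim probes, 0 in the fit to the samples of days 3 and 30 alone, 0 with slide as a fixed or random block, 0 without sheep 2, 0 without sheep 3 and 5577 without sheep 5. It was 0 without day 3, day 30 or day 60 of sheep 2 and without day 3, day 30 or day 60 of sheep 3, 906 without day 60 of sheep 5 and 4474 without day 30 of sheep 5. The higher and lower probes numbered 208 and 46 after quantile scaling, 908 and 456 after median scaling, 521 and 330 after normexp and quantile scaling and 2219 and 912 in the authors' table. CUST_32966_PI425336670 did not pass after quantile scaling (-1.954, adjusted p = 0.0521) or after normexp and quantile scaling (-1.463, adjusted p = 0.118). Nor did it in the authors' table (-1.487, adjusted p = 0.067). The table shared 1171 of the higher and 179 of the lower probes called in the scanner values, against 124 and 8.43 for independent sets. The table's columns of days 3 and 30 match the scanner files, so this overlap is no separate support. Without its slide 1 columns, with sheep 5 as the only sample of day 3, the table gave 13 probes.

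**Figure D2:**
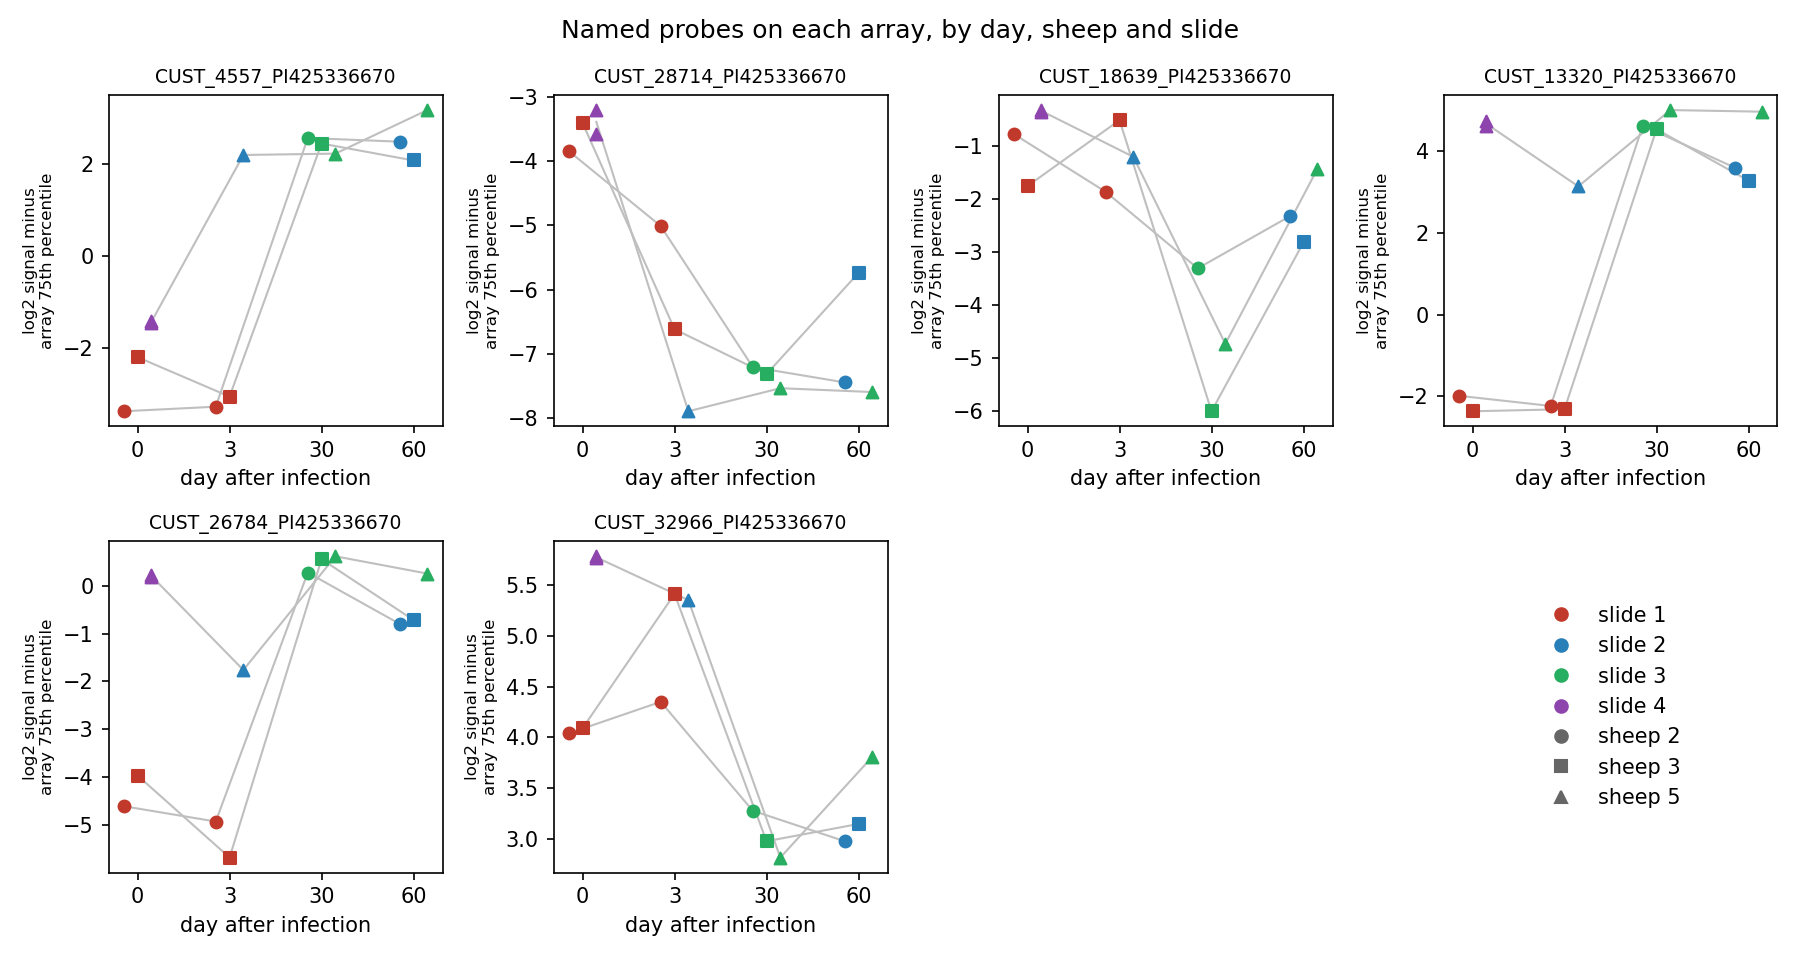
Points give the log2 signal minus the 75th percentile of each array (vertical axis) by day after infection (horizontal axis) for the 6 named probes past the threshold, coloured by slide and shaped by sheep, with grey lines joining the days of a sheep. CUST_13320_PI425336670 lies between -2.37 and -1.99 on slide 1 and between 3.14 and 5.01 on the other slides.

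At day 3 no probe differed from day 0 at the threshold in the scanner values. With limma, 0 of 33595 probes passed, and 1635 had an unadjusted p under 0.05, against 1680 by chance. Probe CUST_38400_PI425336670 had the smallest adjusted p (0.315), with a change of -2.11 (SE 0.23). It was well above background on 1 of the 3 arrays of day 3, so this change is partly set against background. Probe CUST_27187_PI425336670 had the same adjusted p and was well above background on all 4 arrays of day 0 and on none of day 3, a difference of at least 2.44-fold. The probes with higher values and the smallest p were CUST_39359_PI425336670, at 0.97 (SE 0.18), and CUST_39944_PI425336670, at least 1.11-fold above a day 0 level not well above background, both with an adjusted p of 0.974. Within slide 1, where days 0 and 3 of sheep 2 and 3 lay together, 0 probes passed and 1567 had an unadjusted p under 0.05, in a fit with 1 residual degree of freedom. The fit with slide as a fixed block passed 9 probes, without sheep 5 also 9, without day 0 of sheep 5 52 and without day 3 of sheep 5 14.

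The authors' table gave another count for day 3. There, 1284 probes differed from day 0, 201 higher and 1083 lower. In the table the day 3 columns of sheep 2 and 3 match their slide 1 scanner files, whereas the day 0 columns of the same sheep do not. Without these 2 day 3 columns, with sheep 5 as the only sample of day 3, the table gave 71 probes, 20 higher and 51 lower, of which 46 lower and 0 higher were among the 1284. The table count was 1023 with no sheep block, 0 without sheep 2, 0 without sheep 3 and 8154 without sheep 5.

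At day 60 no probe passed against day 0 in the scanner values, although 5995 had an unadjusted p under 0.05 in the limma fit, against 1680 by chance. The smallest adjusted p was 0.154, for CUST_41133_PI425336670, with a change of 1.78 (SE 0.18) and values of 1.92, 1.38 and 2.04 in sheep 2, 3 and 5. Probe CUST_13001_PI425336670 had a change of 1.70 (SE 0.21), CUST_6616_PI425336670 (well above background on 1 of the 3 arrays of day 60) of -1.30 (SE 0.17) and CUST_33843_PI425336670 of -1.12 (SE 0.16), all with an adjusted p of 0.173. Under slide as a fixed block 31 probes passed, all lower, with array weights 3838 (2522 higher, 1316 lower), and without sheep 5 1487 passed. Of single samples, 188 probes passed without day 0 of sheep 5, 13 without day 3 of sheep 5 and 219 without day 30 of sheep 5. By the authors' table, 35 probes passed (10 higher, 25 lower), and without its slide 1 columns 190 (91 higher, 99 lower).

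Single probes with large changes in the table without slide 1 columns were low or high at day 0 in all 3 sheep. CUST_4557_PI425336670 rose by 3.34 (SE 0.24, adjusted p = 0.00828) at day 30 and by 3.51 (SE 0.24, adjusted p = 0.0054) at day 60, whereas with all columns of the table the rise at day 30 did not pass (adjusted p = 0.104). CUST_8056_PI425336670 fell by 1.71 on the log2 scale at day 30 (SE 0.17, adjusted p = 0.0189), and CUST_34775_PI425336670 fell by 1.46 at day 30 (SE 0.15, adjusted p = 0.0189) and by 2.04 at day 60 (SE 0.15, adjusted p = 0.00598). In the scanner values the change of CUST_8056_PI425336670 at day 30 was 0.43 (adjusted p = 0.732), and that of CUST_34775_PI425336670 was 0.67 at day 30 (adjusted p = 0.556) and -0.04 at day 60 (adjusted p = 0.981). For CUST_8056_PI425336670 the scanner values from day 0 to day 30 went from -1.71 to -0.02 in sheep 2 and from -0.75 to 0.35 in sheep 3. In sheep 5 they went from 2.30 and 2.33 on the 2 arrays of day 0 to 0.82. The table has -1.59 for sheep 5, but its columns match the same scanner files, so this is no separate support. The fall in sheep 5 also sets slide 3 against slide 4, and at day 3, on slide 2, the value was -0.30. The origin of the table's day 0 columns of sheep 2 and 3 is unknown.

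Between day 30 and day 60 no probe passed the threshold. For sheep 2 and 3 this contrast sets slide 2 against slide 3, and only sheep 5 had both days on the same slide. With limma 0 probes passed, 1426 had an unadjusted p under 0.05, against 1680 by chance, and the smallest adjusted p was 0.0502. It belonged to CUST_21797_PI425336670 and CUST_1247_PI425336670, which were well above background on all 3 arrays of day 30 and on none of day 60. Their signals at day 60 were at least 1.14-fold and at least 1.75-fold below those at day 30. CUST_28626_PI425336670 had a change of 2.28 (SE 0.37, adjusted p = 0.509) and CUST_24261_PI425336670 of 1.09 (SE 0.21, adjusted p = 0.654). With no sheep block on all arrays 6 probes passed, all lower, without sheep 5 123, without day 30 of sheep 5 73 and without day 0 of sheep 3 3. The authors' table gave 0.

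**Figure D3:**
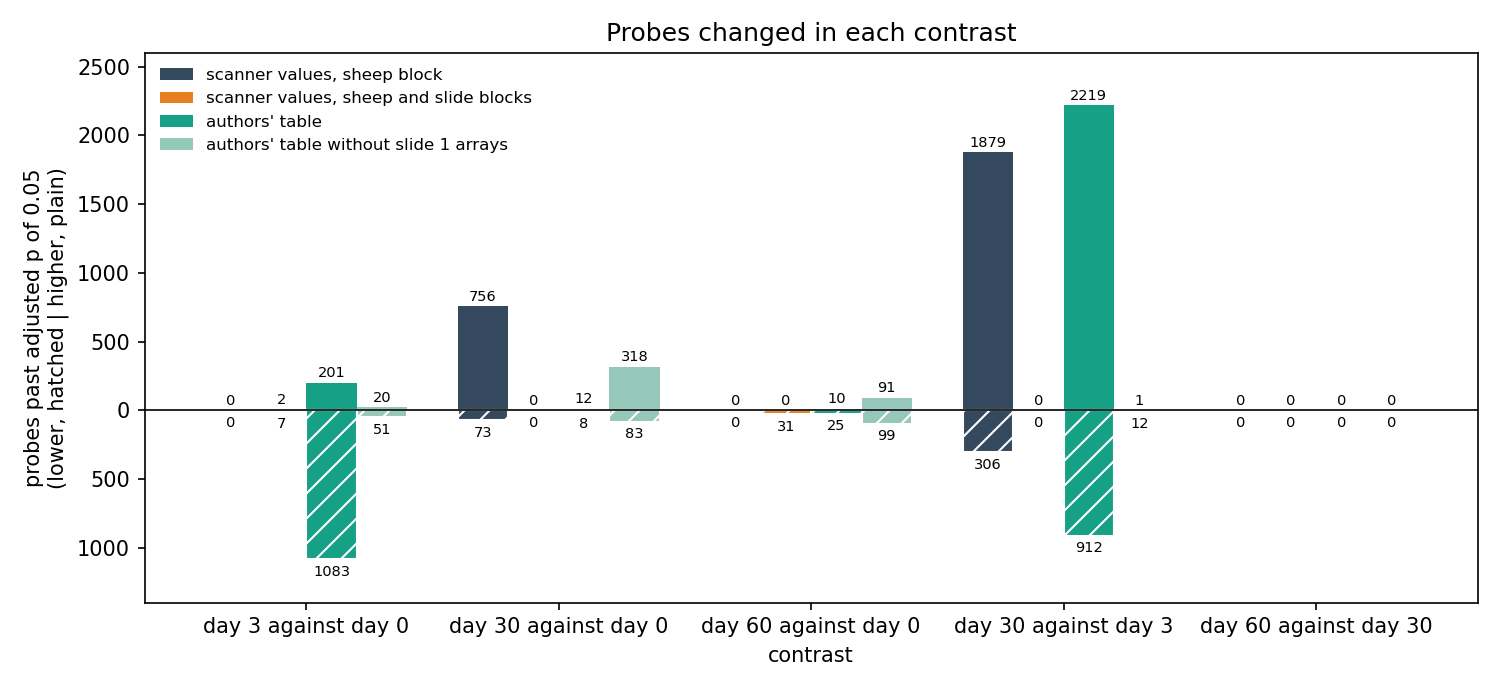
Bars give the number of probes past an adjusted p of 0.05 in each contrast (horizontal axis), higher upwards and lower downwards (hatched), in the scanner values with the sheep block, the scanner values with sheep and slide blocks, the authors' table, and that table without the slide 1 columns. Day 30 against day 3 has 1879 higher and 306 lower probes in the scanner values with the sheep block and 0 with the slide block.

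Over the 4 time points together 1 probe passed the moderated F-test, CUST_27371_PI425336670 (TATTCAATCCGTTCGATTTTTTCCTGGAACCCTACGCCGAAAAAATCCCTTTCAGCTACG), with an adjusted p of 0.0455. It stood highest at day 30, at -3.66, against -5.73 at day 0, -5.60 at day 3 and -5.08 at day 60, and on slide 3 in sheep 5 at -3.08 at day 30 and -4.46 at day 60. Outside day 30 it was not well above background on any array of sheep 2 and 3, so its levels there are at background. 8041 probes had an unadjusted p under 0.05 in the limma F-test. The count was 0 with no sheep block, 11 with slide as a fixed block, 0 with slide as a random block and 1013 in the authors' table. It was 3760 without sheep 5, 1223 without day 0 of sheep 5, 698 without day 3 of sheep 5 and 2311 without day 30 of sheep 5, and 0 without sheep 2, without sheep 3, or without any 1 of the other 9 samples.

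The sheep differed in how far their changes went together. Across probes, which are not independent replicates, the changes from day 0 to day 30 correlated with r = 0.612 between sheep 2 and 3, 0.093 between sheep 2 and 5 and 0.099 between sheep 3 and 5 in the scanner values. From day 0 to day 3, where sheep 2 and 3 each had both days on slide 1, the 3 values were 0.046, 0.038 and 0.01. From day 30 to day 60, with no array on slide 1, they were 0.666, 0.039 and 0.068, where sheep 2 and 3 changed from slide 3 to slide 2 and sheep 5 stayed on slide 3. From day 3 to day 30 the scanner values gave 0.723, 0.181 and 0.346, and from day 0 to day 60 they gave 0.553, 0.168 and 0.099. In the authors' table the changes from day 0 to day 3 correlated with r = 0.735 between sheep 2 and 3, 0.322 between sheep 2 and 5 and 0.255 between sheep 3 and 5. From day 0 to day 30 the values in the table were 0.483, 0.066 and 0.162, and from day 0 to day 60 they were 0.514, 0.345 and 0.275.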

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

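Among the tests given here, those on slide 1, on the 2 unmatched columns of the authors' table and on a GC correction were chosen after the results were seen. The tests on spot position and regrouped samples were fixed before their results were seen.

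The first pattern lies in the authors' table, outside the main comparisons. Its day 0 columns of sheep 2 and sheep 3 had rank correlations of 0.94659 and 0.92712 with their own scanner files, whereas the other 11 columns had at least 0.99989. The processing of the other columns kept the ranks, also for day 3 of sheep 2 and 3 on slide 1 (0.99995 and 0.99989). The higher of the 2 values, 0.94659, lies below these. The tables thus argue against the same array put through a processing that keeps the ranks. A processing of these 2 arrays alone that alters the ranks was not tested. A column of sheep 2 that belongs to sheep 3, or the reverse, is argued against as well. This used the 200 probes that differed most between sheep 2 and 3 at days 30 and 60. Their difference between these sheep at day 0 in the table correlated with that at the later days with r = 0.786. Sheep 5 did not enter this test. However, 9 probes of the table separated all 5 columns of sheep 5 from the other 8, these 2 among them, by at least 4-fold with no overlap. These probes argue against either column belonging to sheep 5. Among the other scanner files, the 2 columns ranked closest to day 60 of sheep 2 (0.9874) and of sheep 3 (0.9833). Such a match need not name the sheep, because the column for day 30 of sheep 2 was closest to day 30 of sheep 3 (0.9815). Another hybridisation of the same RNA, or of other RNA of these animals, stays open and was not tested.

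The second pattern was the 1284 probes that changed at day 3 in the authors' table, against 0 in the scanner values. Of the probes called in the table from sheep 2 and 3 alone, the median change in sheep 5 in the same direction was 0.116 on the log2 scale, against 0.664 in sheep 2 and 3, a ratio of 0.175. An effect of slide 1, which held day 3 of sheep 2 and 3, would give a low ratio. So would the choice of probes by their changes in sheep 2 and 3, so the ratio does not decide between these. The day 0 columns of sheep 2 and 3 in the table do not match the slide 1 scanner files and are of unknown origin. In sheep 5 the contrast sets slide 2 against slide 4, so its change is also one between slides. Of the 1284 probes themselves, in whose calling sheep 5 took part, the ratio was 0.487 (0.522 against 1.071), which lies between the bounds, so slide 1 and time cannot be told apart for them. Spot position, in broad bins and over all tested probes, accounted for 0.187 of the variance of the mean change of sheep 2 and 3. This is too little for a broad position trend to be the whole of that change. Position among the 1284 probes was not tested. Of the 8154 probes, 5683 kept their sign in sheep 5, a share of 0.697, against 0.499 expected from the signs of all probes in sheep 5. A response to the infection in sheep 2 and 3 that was weaker in sheep 5 stays open.

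The third pattern was the 829 probes that changed at day 30 in the scanner values. Of 4181 probes called from sheep 2 and 3 alone, the median change in the same direction was 0.2 in sheep 5, which has no array on slide 1, against 1.596 in sheep 2 and 3, a ratio of 0.126. In the authors' table, whose day 0 columns of sheep 2 and 3 are not those of the scanner files, the ratio for the same contrast was 0.605. It was taken over another set, the 1219 probes called there. An effect of slide 1 would lower the ratio in the scanner values. So would the choice of probes by their changes in sheep 2 and 3, so the ratios do not decide between these. In addition, no slide held both days, and sheep 5 changed from slide 4 to slide 3, so its change is also one between slides. Of the called probes themselves, in whose calling sheep 5 took part, 828 with a value in every sheep had a ratio of 0.578 (0.979 against 1.692), and the falls had a median change of -1.001 in sheep 5, next to -0.899 in sheep 2 and -1.097 in sheep 3. This lies between the bounds, so slide 1 and time cannot be told apart for the called probes. The share with the same sign in sheep 5, the measure tried first, was 0.618 and lay between the bounds set for it. It was 0.666 for the rises, against 0.568 of all probes higher in sheep 5, and 0.386 for the falls, against 0.432 of all probes lower. The slide block had no power to separate slide from time in the simulation. GC content is argued against as the whole cause (741 probes after a GC correction within each array). Spot position, in broad bins and over all tested probes, accounted for 0.0749 of the variance of the mean change of sheep 2 and 3. The scanner software had already removed spatial trends, so this argues only against a broad position trend left in the signal. Finer position effects, or those among the called probes, were not tested. A response to the infection, stronger in sheep 2 and 3 than in sheep 5 or alike in part of the probes, stays open as untested, because every day 30 array lay on slide 3.

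Regrouping the samples bears on the counts only in part. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. Of these, 4 part the days of all 3 sheep and the rest part those of only 1, so they are not equal alternatives to the real split. For day 30 against day 0 the real split gave 829 probes (1 split of 10 gave as many) and the highest other 2, and for day 30 against day 3 it gave 2185 (1 of 10) and the highest other 1, which in both contrasts was also the highest among the other 3 splits that part all 3 sheep. For day 3, the real split gave 0 (10 of 10 splits gave as many) and the highest other 297, which set both days of sheep 2 and day 3 of sheep 3, all on slide 1, against day 0 of sheep 3, also on slide 1, and both days of sheep 5. For day 60 against day 0 and day 60 against day 30 the real split and the highest other gave 0 (10 of 10 splits each). For the change over the 4 time points, the days were shuffled over all 12 samples and not within each sheep, so the pairing was not kept. There, 16 of 100 regroupings gave at least the 1 probe of the real grouping, and the highest other gave 1662, so chance could not be excluded. Whether the regroupings with many calls follow a structure of the samples other than time was not tested.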

How the results depend on the processing

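Of the alternatives, the fits without slide 1 or without day 0 of sheep 2 and 3, the table fits other than the plain one, the GC correction and the single samples left out were chosen after seeing the data. Where no cause is given below, the cause was not tested. Counts over the 4 time points are given as F counts. The main counts were 1 (F), 0 (day 3 against day 0), 829 (day 30 against day 0), 0 (day 60 against day 0), 2185 (day 30 against day 3) and 0 (day 60 against day 30), and counts within 1.5 times of these are not listed.

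With no replicate block, that is without the pairing by sheep, the counts were 0 (F), 1 (day 30 against day 0), 0 (day 30 against day 3) and 6 (day 60 against day 30), and no other count changed. With slide as a fixed block they were 11 (F), 9 (day 3), 0 (day 30 against day 0), 31 (day 60 against day 0) and 0 (day 30 against day 3), with a loss of 3 residual degrees of freedom. With slide as a random block the F count and both day 30 counts were 0. The fits within slide 1 (day 3, 1 residual degree of freedom) and within slide 3 (day 60 against day 30, with 1 sample of day 60 and 2 residual degrees of freedom) gave 0, and were too small to tell. Within slides no other contrast had residual degrees of freedom.

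Quantile scaling gave 2 probes at day 3, 2 at day 60 against day 0 and 254 at day 30 against day 3. Median scaling gave 0 (F), 1364 (day 30 against day 3) and 5 (day 60 against day 30), and normexp with quantile scaling 16 (F), 265 (day 30 against day 0) and 851 (day 30 against day 3). With no filter on dim probes the counts were 2 (day 30 against day 0), 1 (day 60 against day 0) and 0 (day 30 against day 3), and with the filter on all arrays 756 (F) and 1 (day 60 against day 0). A trended and robust prior gave 415 (F). Array weights gave 6560 (F), 6045, 3838, 6699 and 214 for day 30 and day 60 against day 0, day 30 against day 3 and day 60 against day 30. Fits to 2 time points alone, with fewer samples, gave 0 for both day 30 contrasts. The repeat array of sheep 5 alone gave 0 (F) and 1 (day 60 against day 30). At an adjusted p of 0.1 the counts were 2568 (F), 3032 (day 30 against day 0), 5760 (day 30 against day 3) and 6 (day 60 against day 30).

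Without slide 1 the counts were 0 (F), 314 (day 30 against day 0, 77 higher and 237 lower), 192 (day 60 against day 0, 28 higher and 164 lower) and 1 (day 30 against day 3), against 756 higher and 73 lower at day 30 with slide 1. This fit left sheep 5 as the only sample of days 0 and 3. Without day 0 of sheep 2 and 3 they were 0 (F), 0 (day 30 against day 0) and 3696 (day 30 against day 3), with sheep 5 as the only sample of day 0. The authors' table gave 1013 (F), 1284 (day 3), 20 (day 30 against day 0) and 35 (day 60 against day 0), without its slide 1 columns 98, 71, 401 and 190 in that order and 13 (day 30 against day 3), with sheep 5 as the only sample of day 3, and with no replicate block 755, 1023, 57 and 36. With 1 sheep or 1 sample left out, the scanner counts ranged from 0 to 3760 (F), 52 (day 3), 4182 (day 30 against day 0), 1487 (day 60 against day 0), 5577 (day 30 against day 3) and 123 (day 60 against day 30), and with 1 sheep left out of the table from 0 to 8031, 8154, 1219, 139, 11158 and 336. Some of these fits leave a time point of the scanner values with 2 samples.

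Of the values of named probes under the alternatives, 492 kept their direction and side of the threshold, 149 kept their direction and no longer passed, 45 kept it and newly passed, and 8 changed sign. With slide as a fixed block CUST_4557_PI425336670 at day 30 was at -1.53. At day 3, CUST_39359_PI425336670 was at -0.52 in the table with or without the sheep block, and between -1.034 (table without sheep 5) and 1.137 (scanner values without sheep 5) with a sheep or sample left out, including -0.227 and -0.311 in the table without sheep 2 and 3. At day 60, with a sheep or sample left out, CUST_13001_PI425336670 ranged from -0.05 to 1.929 and CUST_33843_PI425336670 from -1.198 to 0.06, with the turned signs in the table without sheep 5. Gene list shifts and the mean of the probes of a gene were not run, because the files do not pair probes with genes. Signal over background limited all fits on slide 1, where as few as 63.55% of spots were well above background.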

Other observations

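The tests on array splits, on individual sheep and on slide 1 probes in this part were chosen after the data were seen, and the test on AU-rich elements was fixed before its result was seen.

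More single probes separated a sheep than a day from the other arrays. In the scanner values, 21 of 33028 probes separated all 5 arrays of sheep 5 from the other 8 by at least 4-fold with no overlap, 17 of them lower and 4 higher in sheep 5. For sheep 3 there were 10 such probes (4 higher, 6 lower) and for sheep 2 there were 4 (1 higher, 3 lower). None separated day 0, day 3, day 30 or day 60 from the other days, nor days 30 and 60 from days 0 and 3. Among 100 random splits of the arrays for each size, the median was 0, with highest values of 1 for sheep 2, 1 for sheep 3 and 0 for sheep 5. For smaller groups the highest value was larger, up to 23 for the size of day 3 and of day 30. In the authors' table the numbers were 9 for sheep 5, 5 for sheep 3 and 2 for sheep 2, again with none for the days. The arrays of sheep 5 lay on slides 2, 3 and 4, of which slides 2 and 3 also held arrays of the other sheep. The arrays of a day, except day 30, lay on at least 2 slides, and the sizes of sheep and day differences over all probes were not compared.

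Slide 1 separated its arrays from the others for more probes than any sheep did. In the scanner values 130 probes were at least 4-fold lower on all 4 arrays of slide 1 than on every other array, and none were higher. The highest of 100 random splits of this size was 3. These probes had a median of -3.72 at day 0 and -3.41 at day 3 of sheep 2 and 3, and of 0.61 on the other 9 arrays. In the authors' table the 126 of them listed had a median of 6.21 (log2) in the day 3 columns of sheep 2 and 3 and of 9.39 in their day 0 columns, next to 9.25 in the other 9. Likewise 130 probes of the table were at least 4-fold lower in the 2 day 3 columns of sheep 2 and 3 than in all other columns. In both sets were 70 probes, against 0.508 for independent sets. The sets are not independent, because these 2 columns and most others match their scanner files, so the overlap is no separate support. Of the 130 scanner probes, 8 were among the 829 called at day 30 against day 0. Among the 2185 called at day 30 against day 3 there were 20. In each contrast 33594 probes were tested, and both shares of the 130 lie above the share called of all probes. The difference was not tested, and the counts do not measure how far slide 1 entered the calls. A further 9 probes, CUST_4557_PI425336670 among them, were at least 4-fold higher on all 7 arrays of slides 2 and 3 than on all 6 of slides 1 and 4, and 1 probe separated the 2 arrays of slide 4 from the other 11, within the highest of 16 among random splits of that size.

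Changes in different sheep, each with a slide 1 array on 1 side, also went together. Across probes, day 0 minus day 30 of sheep 2 in the scanner values correlated with day 3 minus day 0 of sheep 3 in the table with r = 0.445, and the same values of sheep 3 with those of sheep 2 in the table with r = 0.505. Against day 3 minus day 0 of sheep 5 in the table, the values were 0.111 and 0.122. The table's day 0 columns of sheep 2 and 3 enter these changes and their origin is unknown, so a source of the correlation other than slide 1 stays open. Pairs of probes with identical sequences, 342 in number, gave correlated changes in each contrast, from r = 0.445 at day 3 against day 0 to 0.796 at day 30 against day 3 in the scanner values.

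A hypothesis set beforehand was that transcripts with AU-rich elements, sequence motifs of short-lived messages such as those of cytokines, change at day 3. The motif (UUAUUUA followed by a pair of A or U bases) was found in 103 of 33032 probes. Their median changes from day 0 to day 3 were 0.06 in sheep 2, -0.12 in sheep 3 and 0.00 in sheep 5, and 0 of the 3 lay outside the central 95% of 10000 random probe sets matched on GC content and signal (-0.04 to 0.08, -0.15 to 0.09 and -0.08 to 0.07). The predicted shift of the median was thus not seen, because none of the 3 sheep showed a shift beyond that of the random sets. The hypothesis itself stays undecided. The probes with the motif went both ways. In sheep 2, 59 were higher and 44 lower, in sheep 3 33 and 70, and in sheep 5 51 and 52. A median does not decide whether single probes changed in opposite directions, and this was not tested. A probe covers 60 bases, and motifs outside the probes were not searched.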
